A study of Mus musculus with 4 samples.

How the data were processed

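The data are 4 single-cell RNA libraries of digested RAW-112 tumours, 1 for each of untreated and reprogrammed on day 5 and day 10. Per the labels, live CD45.1+ host immune cells and live CD45.2+ tumour cells were sorted and pooled 1 to 1 before the 10x Genomics single cell 5′ v2 protocol. For each library the authors deposited a matrix of raw UMI counts per gene and barcode with lists of barcodes and genes, so the unit is counts without normalisation. The matrices came from Cell Ranger 6.1.1 in 3 libraries and 6.1.2 in the day-10 library labelled reprogrammed, per the file headers, with mm10 as the genome build in the submitters' processing notes. Annotation, aligner settings and the rule that chose barcodes are not given in the sources used here. Every library lists 11000 barcodes and 32285 genes, and the number of barcodes is the same in each, so a barcode was not taken for a cell without further filters. The other deposited files list barcodes and gene names as text and hold no measurement. Gene coordinates were taken from GENCODE M21 on GRCm38, which held 32158 of the 32285 gene identifiers (99.6%).

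Groups were taken from the titles and treatment labels and never from the values. No library was moved to another group. Since each group holds 1 library, no p-value, no standard error between tumours and no count of changed genes over all genes is given, and numbers of list members past 2-fold only describe the list. All intervals are at 95% and cover counting error only.

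Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which passed 6157, 4998, 6464 and 6893 barcodes. Doublets were scored per library with Scrublet in scanpy at an expected rate of 6%. It marked 5, 46, 5 and 0 barcodes, far below that rate, so the removal of doublets has in effect not worked. Counts were scaled to 10000 UMIs per cell and log-transformed. From 2000 variable genes, without immunoglobulin and T-cell receptor segment genes, mitochondrial, ribosomal, Xist and Y-linked genes, 30 components and 15 neighbours were used for Leiden clustering at resolution 1, with all libraries together and without batch integration. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

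Of 26 clusters 22 were named from 18 marker lists fixed before the data were examined, 10 of them B-lineage-like and 3 T-like. A cluster took the class with the highest mean over its best 5 markers. It stayed unnamed with fewer than 3 detected markers (in at least 10% of its cells and at least 2-fold above the rest), with no own marker among its top 10 genes, or with at least as many markers of another class there. A cluster led by another class was called mixed where its B-lineage marker level was at least 33.3% and its median depth at least 50% of those of the B-lineage clusters. B or plasma clusters with Xist at 50 CPM (UMIs scaled to a total of 1000000) or more were kept apart. The mixed rule, the Xist limit and the comparison with other classes' markers were set after the clusters had been seen. Several unnamed clusters were kept out of the compared classes. A cluster of 143, 8, 4 and 18 cells had genes of the leukaemia cells (H19 and Ebf1) among its top 10. It stayed unnamed because it held as many markers of another class there as B-lineage markers. A cluster of 5, 0, 3 and 53 cells had the osteoclast genes Ctsk, Acp5 and Mmp9. The others were clusters of 19, 343, 89 and 2102 shallow cells with histone genes and of 1, 64, 56 and 291 cells. Xist-positive B or plasma cells (4, 19, 63 and 39) were also kept out of the compared classes but count among named cells. They came from a cluster of 82 cells with Xist at 92.3 CPM and genes of the leukaemia cells (Vpreb2, H19, Ebf1) among its top 10, which holds no plasma cell marker there, and a cluster of 43 cells with Ms4a1, Iglc2 and Jchain. The leukaemia lineage is the B-lineage-like and mixed cells together, a class added after the data had been seen.

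For each class and library UMIs were summed and expressed as CPM of the class total. The log2 ratio of 2 libraries was taken with 1 UMI added to each sum, with the exact conditional interval of a ratio of Poisson counts. Comparisons were reprogrammed over untreated within each day and day 10 over day 5 within each treatment, in B-lineage-like, mononuclear phagocyte-like and T-like cells and in whole libraries. A model that adds treatment and day over the 4 libraries was left out, since the 2 treatments were compared within each day. A list's median was taken over members with at least 50 UMIs in the pair, given an interval from 2000 Poisson redraws, and ranked among 10000 random lists of the same size matched on expression. The 20 lists with medians and a list of origin genes were fixed before the data were examined. Clec7a and Mx1 of these lists are not analysed here.

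Named genes follow a rule fixed before the data were examined. Among genes with at least 50 UMIs in the pair on each day, at least 20 CPM in a library of each day's pair and a log2 ratio of at least 1 in size with the same sign on both days, up to 12 each way are taken by the smaller of both sizes. Up to 5 each way are taken for day 10 over day 5, and 3 each way with opposite signs on the 2 days. Immunoglobulin and T-cell receptor segment genes, mitochondrial, ribosomal protein, Xist, Y-linked, Gm and Rik genes are left out. Each list gives up to 4 members, and a fixed set of genes, among them Cebpa, Spi1, Itgam, Cd14, H2-Ab1, Cd86, Cd274 and Ptprc, is always looked at; some genes that were looked at are not reported here. Other genes in the text, such as the members of the mixed cluster, were chosen after their values were seen. Where a pair had under 100 cells on a day, the rule uses the other day alone, and no pair of the 3 main classes was that small.

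Free RNA was profiled from barcodes under 1000 UMIs. Its upper share was bounded by Xist in leukaemia cells and by 6 B-lineage genes (Vpreb1, Vpreb2, Vpreb3, Igll1, Cd79a and Cd79b) in host cells, at 14.0%, 18.2%, 15.1% and 23.1% in T-like cells and 76.7%, 47.4%, 68.7% and 35.0% in phagocyte-like cells, where doublets add to it. These profiles may also hold RNA of damaged cells, which was not tested. An unnamed cluster of kept cells with a median of 1501 UMIs had Xist at 1301 CPM. Such cells in the profile would raise its Xist, so shares bounded by Xist are upper limits only if the profile is free RNA alone.

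Alternatives fixed before the data were examined were a looser filter (200 genes, 500 UMIs, 20%), a stricter filter (1000 genes, 2500 UMIs, 5%), doublets kept, Leiden resolution 0.5 and 2, classes from each cell's own marker UMIs, TMM scaling (rewritten in Python), scaling without mitochondrial, ribosomal and receptor genes, each cell scaled to the same total, cells thinned to 2000 UMIs, 10 UMIs added, and list members from 10 or from 200 UMIs. The limits used in the assignment by each cell's own markers were not fixed beforehand, and several versions were tried with the data at hand. Chosen after seeing the data were leaving out the top 6% of doublet scores, subtracting free RNA, adding the mixed cluster to B-lineage-like cells, leaving out phagocyte-like cells above 1000 CPM of the B-lineage genes, and counting cells with myeloid genes and no Xist among cells of at least 10000 UMIs thinned to that depth. The steps were tested on simulated data in 20 runs with 200 genes altered. The simulated sums were drawn from Poisson distributions without variation between cells. The counting intervals assume the same distribution, so their coverage here says nothing about variation between cells in the real data, and neither do the other rates below. Ratios of 2-fold were recovered to within 0.0087 and of 4-fold to within 0.0205 on the log2 scale, list medians for a true value of 1 came out at 0.893 in T-like and 0.953 in phagocyte-like cells on day 5 and at 0.990 to 1.01 elsewhere, intervals held the true value for 95.3% to 96.6% of genes, and unaltered genes passed the 2-fold rule in 0.0401% to 0.275% of cases except T-like cells on day 5, with 4.61%.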

Results

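The study asked what happens in a tumour when leukaemia cells are driven toward antigen-presenting cells by doxycycline. RAW-112 is a mouse B-cell leukaemia line grown under the skin, and doxycycline is an antibiotic used to switch on introduced genes. The labels do not name the factor that was switched on. Tumours were taken on day 5 or day 10 and digested. Live CD45.1+ cells, the immune cells of the host, and live CD45.2+ cells, the tumour cells, were sorted and mixed 1 to 1. The mixture went into droplets for single-cell RNA sequencing from the 5′ ends of transcripts, in which each transcript caught is counted once by a unique molecular identifier (UMI). The 4 libraries are labelled untreated day 5, reprogrammed day 5, untreated day 10 and reprogrammed day 10, with 1 library in each group. Groups are named throughout by these labels, and where 4 values stand in a row they follow this order. Every direction drawn for day 10 rests on the labels of the day-10 pair. Across genes at least 2-fold apart on day 5, interferon lists left out, the day-5 and day-10 log2 ratios of reprogrammed over untreated were negatively correlated in B-lineage-like cells (Pearson r -0.534 over 629 genes) and in T-like cells (-0.273 over 472 genes), and genes are not independent replicates.

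The libraries held 139171510, 96231626, 133854884 and 62093534 UMIs, each over 11000 barcodes. After filtering and removal of called doublets, 6152, 4952, 6459 and 6893 cells were kept. The median depth of cells passing the filter was 22238, 17104, 20597.5 and 2679 UMIs, so over all cells, though not in every class, the day-10 library labelled reprogrammed was the shallowest. Its unnamed cells were 35.7% of those kept, against 2.73%, 8.38% and 2.35% in the other libraries. With 1 library per group the spread between tumours is unknown. Intervals are 95% intervals that cover counting error only, Poisson for counts and exact binomial (Clopper-Pearson) for shares, and no test between groups was made. Expression is given as CPM, the UMIs of a gene in a cell class scaled to a class total of 1000000, and a gene is called higher or lower where its CPM differed at least 2-fold. Gene lists are described by the median log2 ratio of their measured members and by its percentile among 10000 random lists of genes with similar expression.

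The first comparison asks which cell types the tumours held with and without doxycycline. B-lineage-like cells, which carry Vpreb1, Igll1, Cd79a and other genes of early B cells and almost no Xist, made up 96.96% [96.49, 97.38], 72.0% [70.7, 73.3], 74.1% [73.0, 75.1] and 52.2% [50.7, 53.7] of named cells. T-like cells were 0.785% [0.578, 1.04] in the untreated and 11.4% [10.4, 12.3] in the reprogrammed library of day 5. On day 10 they were 8.91% [8.22, 9.64] and 15.7% [14.6, 16.8]. Of all kept cells, unnamed ones included, they were 0.764%, 10.4%, 8.70% [8.02, 9.41] and 10.1% [9.37, 10.8], so most of the day-10 gap among named cells goes with the unnamed cells of the reprogrammed library. NK-like cells, marked by Ncr1 and Gzma, followed the same order with 0.251% [0.140, 0.413], 6.26% [5.57, 7.0], 5.55% [5.00, 6.14] and 12.5% [11.6, 13.5]. Mononuclear phagocyte-like cells were 0.953%, 1.74%, 2.71% and 7.13% of named cells, and dendritic-like cells 0.234%, 1.32%, 0.460% and 2.39%. Neutrophil-like cells stood apart in the day-10 reprogrammed library, at 6.75% [6.03, 7.53] against 0.745% or less in the other 3, and under the stricter cell filter at 1.69% [1.27, 2.21] against 0.150% or less. Their cluster had a median depth of 2163 UMIs and B-lineage markers at 3482 CPM, against 4760 to 7960 in the B-lineage-like clusters. Mast cell or basophil-like cells stood apart in the day-5 reprogrammed library, at 2.09% [1.70, 2.55] against 0.143% or less.

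Because tumour and host cells were sorted and mixed at a set ratio, these shares depend on the sort as well as on the tumour. Host classes, called so by their markers and not by the origin of each cell, numbered 177, 1098, 1263 and 2074. Named cells were 5984, 4537, 6307 and 4429. The counts were far below 1 to 1 in untreated day 5, reprogrammed day 5 and untreated day 10. They came nearer to it in reprogrammed day 10, where 2464 of 6893 kept cells were unnamed and left out. Of these, 2102 lay in a shallow cluster with B-lineage markers at 2953 CPM, so the B-lineage-like share there depends on the naming too. Host classes were scarcest in untreated day 5, so its low T-like share goes with few host cells. Among host classes alone, T-like cells were 26.6%, 46.9%, 44.5% and 33.5%, and phagocyte-like cells 32.2%, 7.19%, 13.5% and 15.2%. NK-like cells were 24.2%, 35.5%, 38.4% and 44.4% of T-like and NK-like cells together. The stricter cell filter lowered the T-like share on day 5 to 0.411% in the untreated and 7.75% in the reprogrammed library.

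**Figure D1:**
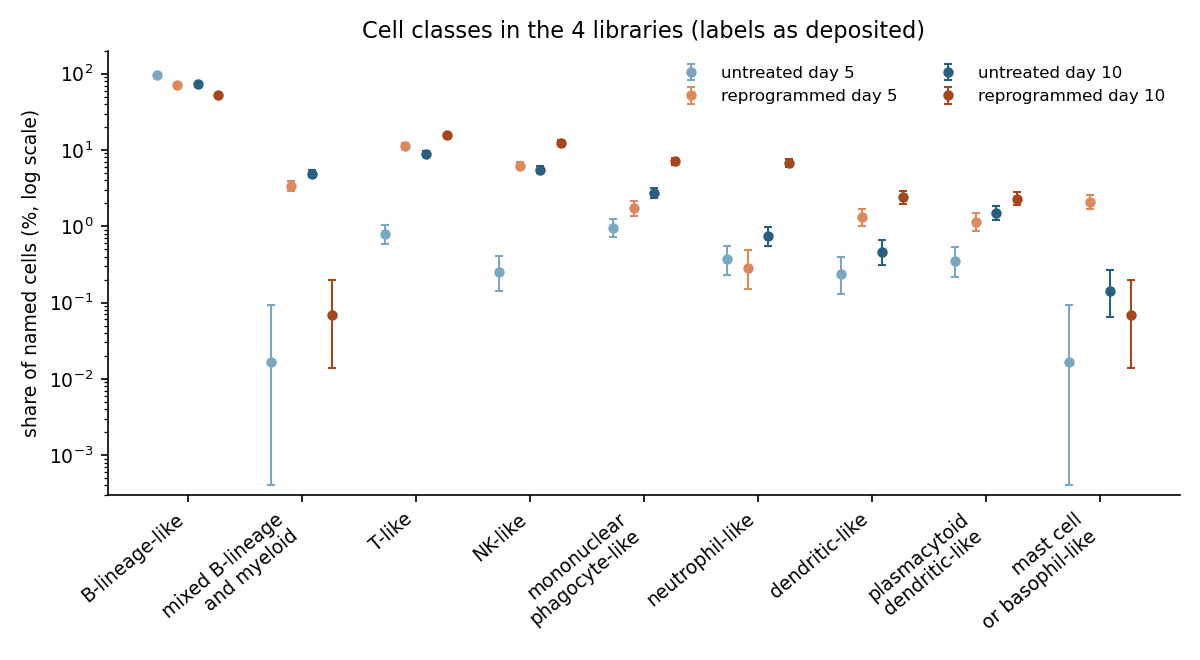
Share of named cells in percent (log scale) for 9 cell classes, with 1 point for each of the 4 libraries and bars for exact 95% binomial intervals. B-lineage-like cells lie between 52.2% and 96.96% in every library, while T-like cells lie at 0.785% in the untreated day-5 library and between 8.91% and 15.7% in the other 3.

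A cluster of cells with both B-lineage and myeloid genes bears on the question whether leukaemia cells took on a myeloid state. Its cells carried Lyz2 (lysozyme) at 4521 CPM in the reprogrammed day-5 library and 8389 in the untreated day-10 library. S100a8, a calcium-binding protein of neutrophils and monocytes, stood at 1774 and 2228, and Prtn3, a granule protease of early myeloid cells, at 317 and 268. The same cells held the surrogate light chain genes Vpreb1 (472 and 494) and Igll1 (577 and 454), as well as Spi1, the myeloid and B-cell transcription factor PU.1 (341 and 304). Cd14 stood at 229 and 130, Itgam at 80.4 and 92.9, Cd74 at 1186 and 1299, and H2-Ab1 at 96.1 and 107. The costimulatory ligand Cd86 was low, at 7.64 and 23.1. Xist, the X inactivation transcript, marked host cells here, with 142 CPM or more in phagocyte-like cells and 3.33 or less in B-lineage-like cells, and in the mixed cells it stood at 3.94 [2.25, 6.41] and 1.10 [0.53, 2.03]. Median depth was 26271 and 29371.5 UMIs.

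These mixed cells were 1 of 5803 leukaemia-lineage cells (0.0172%) in the untreated and 153 of 3420 (4.47% [3.81, 5.22]) in the reprogrammed library of day 5. On day 10 they were 310 of 4981 (6.22% [5.57, 6.93]) in the library labelled untreated and 3 of 2316 (0.130% [0.0267, 0.378]) in the library labelled reprogrammed. Over the whole leukaemia lineage, 18 of the 21 measured myeloid surface and granule genes were higher in the reprogrammed library on day 5 (median log2 ratio 3.75 [3.57, 4.09]). On day 10, 18 of 21 were lower (-3.23 [-3.61, -2.82]). These medians restate the share of mixed cells, since that cluster was named by myeloid markers, among them Lyz2 of this list. B-lineage-like cells without the mixed cells had no list median of this size on either day, and their values are given with the remaining lists below. S100a8 read 0.292, 86.2, 171 and 1.64 CPM, Hp (haptoglobin) 0.0973, 21.3, 28.8 and 0.282, and S100a9 0.726, 43.6, 83.3 and 2.71. Cells with myeloid genes were also counted without clusters, as deep cells with at least 10 myeloid UMIs of 10000 and no Xist. This asks for no B-lineage gene, so host phagocytes without an Xist UMI can be among them. They were 0.336% [0.199, 0.530], 3.32% [2.71, 4.01], 5.45% [4.82, 6.13] and 4.18% [3.32, 5.20] of deep cells. In the day-10 reprogrammed library 56 of these 78 cells lay in the phagocyte-like cluster and 0 in the mixed cluster. Whether these 56 are host cells or leukaemia cells was not determined. Assigning each cell by its own marker UMIs gave mixed shares of 0.635%, 2.72%, 6.56% and 4.12%, so the low value on day 10 in reprogrammed depends on how cells are assigned. This assignment sets no limit on Xist, so droplets with a leukaemia cell and a host phagocyte can be among these mixed cells.

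The leukaemia comparison asks how leukaemia cells of the B-lineage-like class differed with doxycycline. They numbered 5802, 3267, 4671 and 2313 cells with 133564643, 80242554, 109865174 and 39001395 UMIs. On day 5 the interferon response separated the pair. All 13 measured interferon-gamma response genes were higher in the reprogrammed library (median log2 ratio 3.20 [3.02, 3.44], at percentile 100.0 of the random lists), and so were all 14 type I interferon response genes (3.88 [3.79, 4.09]). Gbp2, a guanylate-binding protein induced by interferon, read 3.20 CPM in the untreated and 140.0 in the reprogrammed library (log2 ratio 5.45 [5.31, 5.59]). Iigp1 read 0.951 and 100.3 (6.71 [6.47, 6.99]), and Isg15, a ubiquitin-like protein induced by type I interferon, 4.86 and 111 (4.52 [4.4, 4.64]). On day 10 the order was not the same. The interferon-gamma list had a median below 0 (-0.60 [-0.65, -0.58]), with 3 of 15 members higher, 1 lower and 11 between, and the type I list stood at 0.06 [-0.01, 0.08] with no member 2-fold apart. Gbp2 stood at 461 in the day-10 untreated library and 237 in the reprogrammed library (-0.96 [-0.99, -0.93]), both above the day-5 levels.

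The rule for named genes, with its floor of 20 CPM in a library of each day's pair, took none in B-lineage-like cells as higher, or as lower, in reprogrammed on both days. Several genes were turned around between the days. Lta, which encodes lymphotoxin alpha, read 369, 42.6, 41.0 and 378 CPM, a log2 ratio of -3.12 [-3.17, -3.07] on day 5 and 3.20 [3.16, 3.25] on day 10. Cpt1a, the enzyme that brings fatty acids into mitochondria, read 89.4, 22.1, 14.3 and 59.9, and M1ap 22.9, 3.83, 7.87 and 33.9. The reverse order held for Dntt, the terminal transferase of early lymphocytes (36.5, 131, 108 and 27.3), and for Ly6a, which encodes Sca-1 (0.801, 29.2, 248 and 123). Rag1 and Rag2, the recombinase genes, went with Dntt at 5.02, 15.2, 9.31 and 2.38 and at 4.15, 14.9, 4.25 and 1.10. These 3 were the only members of the 24-gene B-cell programme that were higher on day 5 (list median 0.11 [0.09, 0.13]), and the same 3 were its only lower members on day 10 (-0.26 [-0.30, -0.23]). Spata7 came close to the rule's limits on both days, at 41.3, 85.4, 162 and 320 (1.05 [1.00, 1.10] and 0.98 [0.94, 1.01]).

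On day 5 antigen presentation genes differed less than the interferon lists. Of 20 class I presentation genes 3 were higher on day 5 (median 0.66 [0.64, 0.67]), namely H2-T23 (43.7 and 128 CPM), Psmb10 (66.7 and 182) and Tapbp (25.01 and 65.7), and on day 10 the median was -0.16 [-0.19, -0.13]. Class II presentation genes went both ways on day 5, with 2 of 11 higher and 4 lower (0.08 [-0.21, 0.27]). H2-Aa was higher on both days but scarce (0.704, 3.29, 2.69 and 9.31). In the free RNA of reprogrammed day 10 it stood at 181 CPM, and free RNA made up at most 12.5% of the class's UMIs there by the Xist bound. Free RNA could therefore give all of the H2-Aa seen in that library. H2-Ab1 was lower on day 5 and within 2-fold on day 10 (55.4, 24.2, 25.1 and 40.7). Cd274, which encodes the checkpoint ligand PD-L1, read 4.01, 14.6, 32.2 and 23.9 (1.87 [1.72, 2.02] and -0.43 [-0.54, -0.33]), and Cd40 0.524, 2.95, 7.15 and 15.8. Among myeloid transcription factors the median of 7 measured members was -0.67 [-0.72, -0.61] on day 5 and 0.16 [0.12, 0.21] on day 10. Cebpb read 70.5, 35.0, 150 and 167, Id2 22.03, 11.2, 21.7 and 64.5, and Spi1 71.9, 69.0, 71.2 and 75.1. Cebpa gave 3, 6, 15 and 3 UMIs in the whole leukaemia lineage, and whether an introduced copy would be counted under this gene is not stated in the labels. Cd86 gave 0.103 CPM or less, and Itgam and Cd14 under 1.

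The largest clusters of the B-lineage-like class were not the same in each library: clusters 0 and 3 in untreated day 5 (2617 and 2217 of 5802 cells), cluster 7 in reprogrammed day 5 (1018 of 3267), clusters 2 and 4 in untreated day 10 (1656 and 1520 of 4671) and cluster 5 in reprogrammed day 10 (737 of 2313). Cluster 5 was shallow, with a median of 2618 UMIs against 19781.5 or more in the other B-lineage-like clusters, and had Xist at 9.64 CPM. RNA from lysed cells in the droplets, bounded through Xist, made up at most 1.71%, 2.86%, 1.18% and 12.5% of the class's UMIs. This holds if the barcodes under 1000 UMIs are free RNA only, which was not tested.

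**Figure D2:**
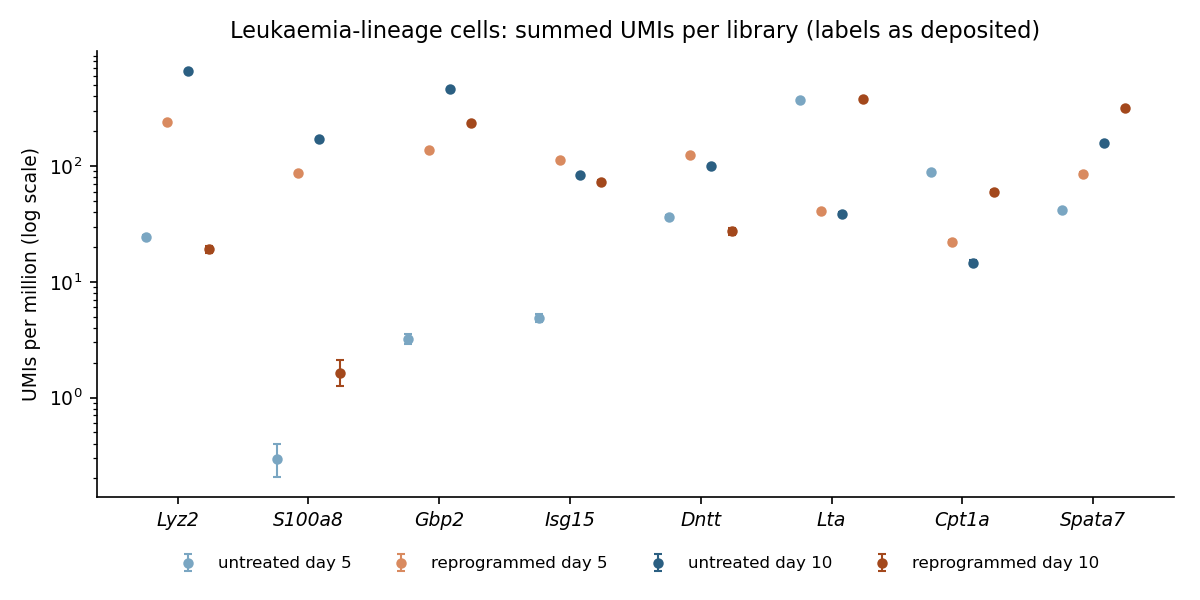
CPM (log scale) of 8 genes in leukaemia-lineage cells, B-lineage-like and mixed cells together, with 1 point per library and bars for Poisson 95% intervals. S100a8 lies at 86.2 and 171 in reprogrammed day 5 and untreated day 10 and at 0.292 and 1.64 in the other 2 libraries, and Lta shows the opposite order with 40.7 and 38.7 against 369 and 377.

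The phagocyte comparison asks how macrophage-like and monocyte-like cells differed. The 57, 79, 171 and 316 cells of this class had Xist at 142 to 202 CPM as a class, unlike leukaemia cells. Their median depths were 5695, 6529, 9012 and 12154 UMIs. Counts per gene do not tell CD45.1 from CD45.2, so the origin of each cell is not known, and converted leukaemia cells could be among them. In reprogrammed day 10, 56 deep cells of the class with myeloid genes had no Xist UMI and 133 had at least 1. The makeup of the class also differed between libraries. At Leiden resolution 2 it was split into clusters of 39, 26, 30 and 287, of 18, 53, 141 and 33 and of 1, 9, 6 and 42 cells. On day 5 interferon response genes were far higher in the reprogrammed library. Cxcl9, a chemokine that draws activated T cells, read 7.98 CPM in the untreated and 862 in the reprogrammed library (log2 ratio 6.44 [5.39, 8.64]), and Cxcl10 read 91.7 and 1498 (4.0 [3.60, 4.49]). Of the interferon-gamma response genes 11 of 12 were higher (median 2.84 [2.54, 3.29]) and of the type I genes 13 of 14 (3.12 [2.84, 3.56]). On day 10 both lists were lower in the library labelled reprogrammed, with 12 of 15 members lower (-1.19 [-1.26, -1.12]) and 14 of 15 lower (-1.77 [-1.90, -1.63]). Cxcl10 then read 776 and 386, Isg15 580 and 144, and Ifit2 122 and 15.5.

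Presentation and costimulation followed in part. Class I presentation genes had a median of 1.00 [0.91, 1.20] on day 5, 9 of 17 higher, and -0.45 [-0.51, -0.35] on day 10. Costimulatory and coinhibitory ligands had 1.16 [0.81, 1.5], 4 of 7 higher, and -0.71 [-0.82, -0.51]. Cd40 read 27.9, 191, 170 and 68.4, Cd86 15.95, 61.0, 82.6 and 48.7, and Cd274 99.7, 226, 269 and 331. Class II presentation genes kept the same sign, with medians of 0.32 [0.13, 0.43], at percentile 96.2 of the random lists and 1 of 10 higher, and 0.72 [0.65, 0.93], 3 of 11 higher. H2-Ab1 stood at 2517 and 2351 on day 5 and at 2221 and 4271 on day 10. H2-DMb2, part of the molecule that loads peptides onto class II, stood at 158, 196, 212 and 619, and the class II transactivator Ciita at 37.9, 86.7, 96.6 and 68.1. The day-5 median of the list was 0.02 with cells thinned to 2000 UMIs and 0.99 with classes from each cell's own markers.

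Medians of lists linked to low oxygen and to suppressive macrophages had the other sign, though most members of the former stayed within 2-fold. Hypoxia and glycolysis genes had a median of -0.92 [-1.04, -0.77] on day 5, 4 of 11 lower, and of 0.75 [0.64, 0.86] on day 10, 4 of 14 higher. Read out singly were Ndrg1 (229, 43.4, 79.5 and 228) and Bnip3 (333, 64.2, 151 and 310). Suppressive myeloid genes had -0.83 [-1.33, -0.50] and 0.62 [0.52, 0.83], but not all members went along. Vegfa, the vascular growth factor, read 148, 30.5, 54.0 and 159, and Thbs1 473, 43.4, 88.3 and 75.5, whereas Spp1 (osteopontin) was higher in reprogrammed on both days at 27.9, 109, 55.1 and 187 (1.89 [1.12, 2.91] and 1.76 [1.47, 2.07]). Phagocytic receptor and lysosome genes stood at 0.39 [0.21, 0.52] and 0.57 [0.50, 0.64], with Ctsl at 495, 130, 179 and 435 and Fcgr1 at 130, 334, 218 and 155.

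Along with Spp1, the named-gene rule took as higher in reprogrammed on both days Clec5a, a myeloid activating receptor (15.95, 69.0, 57.7 and 188), Ccl12 (19.9, 281, 55.6 and 124) and AW112010 (253, 531, 1132 and 2349). Those taken as lower on both days included the B-lineage genes Mzb1 (327, 119, 342 and 90.1), Cd79a (411, 170, 434 and 166) and Vpreb2 (231, 106, 294 and 142). Cells above 1000 CPM of 6 B-lineage genes were 12.3%, 3.80%, 12.9% and 9.49% of this class and far deeper than the rest, and without them the day-10 median of the B-cell programme was 0.19 and no longer -1.44. Classes from each cell's own markers turned Spp1 on day 10 to -1.33 and the suppressive list on day 5 to 1.38. The median of all genes on day 10 was -0.17, and the day-5 pair rests on 136 cells.

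The T-cell comparison asks how host T cells differed in tumours with reprogrammed cells. The 47, 515, 562 and 694 T-like cells had median depths of 2310, 2726, 4959.5 and 3619.5 UMIs, and the 47 cells of untreated day 5 limit every day-5 value. The makeup of the class differed between libraries, with 30, 358, 281 and 252 cells in a cluster marked by Ctla4, Tnfrsf4 and Tnfrsf18, 17, 157, 210 and 379 in one marked by Cd8b1, Ccl5 and Gzmb, and 0, 0, 71 and 63 in one marked by Ifng and Xcl1. Type I interferon response genes were higher in reprogrammed on day 5 in 11 of 12 (median log2 ratio 2.29 [2.0, 2.73]) and lower on day 10 in 10 of 13 (-1.41 [-1.58, -1.25]). The interferon-gamma list had 9 of 12 higher (1.40 [1.12, 1.89]) and then 4 of 13 lower (-0.59 [-0.79, -0.47]). Ifit1, an interferon-induced antiviral gene, read 6.15, 104, 24.0 and 6.41 CPM. Most regulatory T genes stayed within 2-fold (medians 0.31 [0.09, 0.88], 3 of 8 higher, and -0.73 [-0.86, -0.62], 2 of 10 lower), while Foxp3, the master factor of regulatory T cells, read 30.7, 119, 102 and 45.8 and Ikzf2 43.0, 142, 164 and 76.9. Proliferation genes stood at 0.33 [0.08, 0.66] and -0.82 [-0.91, -0.74], with Mki67 at 55.3, 163, 293 and 176.

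Cytotoxic and effector genes differed little as a list. The median was 0.34 [0.10, 0.55] on day 5, with 5 of 20 higher and 3 lower, and -0.35 [-0.48, -0.28] on day 10, with 1 of 22 higher and 2 lower, at percentile 5.86 of the random lists. Adding 10 UMIs to each sum turned the day-5 median to -0.40. Ccl5, a chemokine of effector cells, was higher by the 2-fold rule on day 10 only (2902, 3972, 2602 and 5622). Exhaustion genes stood at 0.07 [-0.63, 0.35] and -0.32 [-0.45, -0.16], with Lag3 at 92.2, 55.9, 342 and 242 and Tigit at 307, 136, 241 and 254, and naive and memory genes at 0.02 [-0.32, 0.27] and 0.28 [0.10, 0.42].

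Among named genes Tiparp (18.4, 57.0, 15.8 and 33.6) and Hist1h3c (36.9, 107, 20.6 and 41.8) passed the rule as higher in reprogrammed on both days, but the untreated day-5 sums were only 3 and 6 UMIs. Their day-5 log2 ratios of 1.23 [0.04, 3.93] and 1.33 [0.39, 3.0] turned to -0.36 for Tiparp with 10 UMIs added and to -3.41 for Hist1h3c with free RNA subtracted. Ifng, which encodes interferon-gamma, and Spc24, a kinetochore gene (55.3, 29.0, 74.9 and 33.0), were lower on both, though the day-5 interval of Spc24 spans 0 (-1.06 [-1.963, 0.27]). Ifng read 5762, 83.8, 4320 and 1919, but 99.6% of its 937 UMIs in untreated day 5 came from 1 of the 47 cells. Without the top 6% of doublet scores its day-5 log2 ratio was 1.39 and no longer -6.10. On day 10 the 5 cells with the most Ifng held 37.0% of its UMIs in untreated and 56.9% in reprogrammed. At least 1 Ifng UMI was seen in 234 of 562 and 228 of 694 cells there. Il13, a type 2 cytokine, read 0, 71.7, 196 and 8.24, and Ly6a 79.9, 331, 670 and 130. Tsc22d3, a glucocorticoid-induced gene, showed the opposite order at 289, 140, 60.5 and 200, as did Pik3ip1 at 86.1, 23, 13.9 and 40.6. The median of all genes on day 10 was -0.16.

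**Figure D3:**
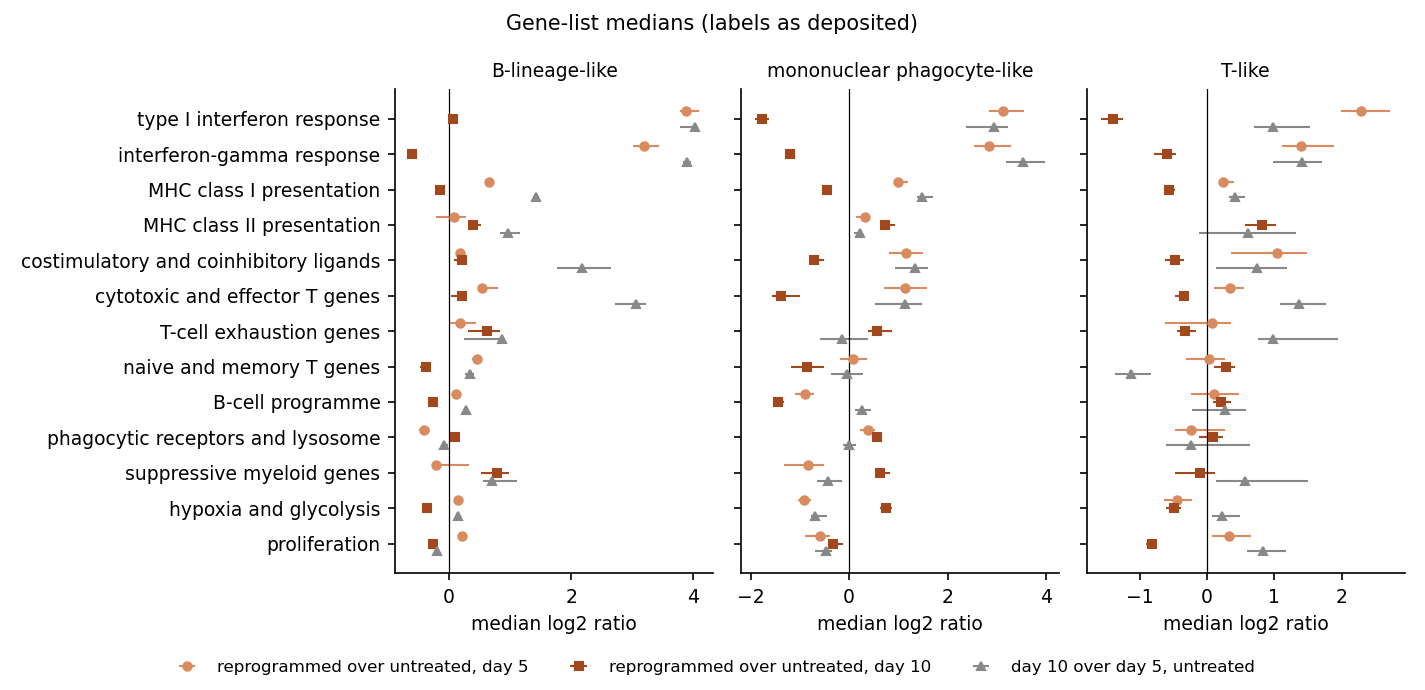
Median log2 ratio (CPM) of 13 gene lists in B-lineage-like, phagocyte-like and T-like cells, with points for reprogrammed over untreated on day 5 and on day 10 and for day 10 over day 5 in untreated, and bars for 95% counting intervals. In B-lineage-like cells the interferon-gamma list lies at 3.20 on day 5 and -0.60 on day 10 for reprogrammed over untreated and at 3.89 for untreated day 10 over day 5.

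The whole-library comparison needs no cell classes but moves with the makeup of the pool. Genes taken by the named-gene rule as higher in reprogrammed on both days included Cd74, the invariant chain of class II molecules (65.8, 249, 369 and 1590 CPM), Ccl5 (7.84, 216, 261 and 990), Il1b (6.21, 25.8, 31.2 and 175), S100a9 (18.2, 66.6, 119 and 541), Lgals3 (9.12, 29.6, 52.3 and 404), Ier3 (7.92, 73.0, 17.9 and 118) and Tnfaip3 (8.35, 39.8, 20.9 and 103). Class II presentation genes had medians of 1.06 [0.99, 1.10], 7 of 12 higher, and 1.79 [1.76, 1.82], 10 of 12 higher. Suppressive myeloid genes stood at 1.51 [1.45, 1.58] and 1.36 [1.17, 1.5], exhaustion genes at 1.59 [1.38, 1.91] and 1.05 [0.95, 1.17], and cytotoxic genes at 4.44 [4.10, 4.68] and 0.50 [0.46, 0.53]. The interferon-gamma list was again split, at 3.48 [3.41, 3.55] with 14 of 15 higher on day 5 and -0.71 [-0.73, -0.67] on day 10. With each cell scaled to the same total, S100a9 on day 5 was at -0.31 and costimulatory ligands on day 10 at -0.01.

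The last comparison asks how tumours differed between day 10 and day 5. In untreated B-lineage-like cells the day-10 library had all 13 interferon-gamma response genes higher (median 3.89 [3.83, 3.96]), 13 of 14 type I genes higher (4.03 [3.78, 4.09]), 15 of 20 class I presentation genes higher (1.42 [1.40, 1.43]) and costimulatory and coinhibitory ligands at 2.18 [1.77, 2.65]. In reprogrammed B-lineage-like cells the interferon-gamma list differed far less (0.46 [0.40, 0.51], 4 of 14 higher) and the type I list stood at -0.13 [-0.18, -0.09]. There, class II presentation (1.56 [1.37, 1.66], 7 of 10 higher) and myeloid transcription factors (1.27 [1.23, 1.31], 5 of 7 higher) were higher and proliferation was at -0.60 [-0.63, -0.58]. By the Xist bound, free RNA could make up at most 12.5% of the class's UMIs in reprogrammed day 10 and 2.86% in reprogrammed day 5. The part of free RNA in these values was not tested. Higher on day 10 under both treatments were Gbp8 (0.382, 3.73, 31.9 and 20.7), Ly6a, Spata7, Rnaset2a (12.8, 15.3, 48.0 and 64.2) and Fas, the death receptor (7.98, 8.46, 28.6 and 28.1). Tnfsf11, which encodes RANKL (35.1, 29.2, 5.63 and 7.90), Rcan2 (38.2, 40.3, 14.0 and 10.9), Tnni2, Efhd1 and Drc7 were lower.

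In phagocyte-like cells the untreated day-10 library had higher interferon-gamma (3.53 [3.19, 3.97]) and type I (2.93 [2.37, 3.24]) lists than day 5, and in the reprogrammed pair both medians were below 0 (-0.53 [-0.59, -0.28] and -2.40 [-2.63, -2.04], 15 of 15 type I genes lower). Apoe (2036, 1349, 448 and 614) and Ms4a7 (126, 138, 29.1 and 62.1), a pair of macrophage markers, were lower on day 10 under both treatments, and Cd9 (25.9, 33.7, 105 and 234) was higher. In T-like cells the medians of cytotoxic and exhaustion genes were above 0 and those of naive and memory genes below 0 under both treatments. The cytotoxic medians were 1.37 [1.09, 1.76] in untreated, 14 of 22 higher, and 0.81 [0.62, 0.95] in reprogrammed, 9 of 21 higher. The exhaustion medians were 0.97 [0.76, 1.95], 6 of 13 higher, and 1.01 [0.85, 1.13], 7 of 13 higher, and the naive and memory medians -1.14 [-1.37, -0.83], 7 of 11 lower, and -0.97 [-1.07, -0.83], 5 of 12 lower. Havcr2, an exhaustion receptor, read 6.15, 8.22, 178 and 118, the chemokine gene Xcl1 6.15, 98.03, 1384 and 919, and Csf2 0, 6.57, 116 and 138, while S1pr1, which lets T cells leave tissues, read 86.1, 122, 30.7 and 35.7. TMM scaling moved the reprogrammed B-lineage interferon-gamma median from 0.46 to 0.29.

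Coordinates of the genes used most are on the GRCm38 build. Lyz2 (ENSMUSG00000069516) lies on chromosome 10 from 117277331 to 117282321 and S100a8 (ENSMUSG00000056054) on chromosome 3 from 90668978 to 90670035. Lta (ENSMUSG00000024402) is at 35203165 to 35205351 on chromosome 17, Dntt (ENSMUSG00000025014) at 41029275 to 41059525 on chromosome 19, and Gbp2 (ENSMUSG00000028270) at 142620602 to 142638008 on chromosome 3. H2-Ab1 (ENSMUSG00000073421) spans 34257689 to 34269419 on chromosome 17 and Ifng (ENSMUSG00000055170) 118441046 to 118445892 on chromosome 10. All 7 are annotated as protein-coding, whereas Xist (ENSMUSG00000086503), on chromosome X from 103460366 to 103483254, is a long non-coding RNA. Counts are per gene, so exons, introns and untranslated regions are not told apart.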

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

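The tests of doublets by Xist and of free RNA by the level of Lyz2 and of Ifng without its top cells were chosen only after the result was seen, as were the leukaemia lineage as a class, the count of deep cells with myeloid genes and the alternatives named here as added. The other tests were set down before their own values were computed, the one on exchanged labels after the mixed cluster and a handful of genes had been looked at. Gene lists, marker lists, comparisons and the remaining alternatives were chosen before the data were examined. Each result in this part stands out because the day-5 pair and the day-10 pair went in opposite directions, and none of these differences between days was tested, as each group is 1 library.

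Leukaemia-lineage cells with myeloid genes were seen in the libraries labelled reprogrammed day 5 and untreated day 10. The day-5 difference in their share (4.46 points) minus the day-10 difference (-6.09 points) is 10.6 percentage points. The myeloid surface and granule list of the leukaemia lineage differs by 6.98 between days. That list difference restates the share and is no separate result, since the mixed cells were named by myeloid markers. An exchange of the labels of the day-10 pair needs negative correlations of both days' log2 ratios across genes. These were -0.534 in B-lineage-like and -0.273 in T-like cells, as an exchange would give if both days share treatment effects. No library was moved. Assigning each cell by its own markers leaves a smaller day-10 difference, with mixed shares of 4.12% in the library labelled reprogrammed and 6.56% in untreated. That assignment sets no limit on Xist, so droplets with a leukaemia cell and a host phagocyte can be among its mixed cells. It therefore decides nothing on the labels. For the cells of the mixed cluster, droplets holding a leukaemia cell and a host phagocyte are argued against by Xist. It reached only 7.31% and 0.836% of the level that the cluster's Lyz2 would bring along in reprogrammed day 5 and untreated day 10. Free RNA of host myeloid cells is argued against by Lyz2 at 31.2 and 36.7 times the level of pure free RNA, which is the most that free RNA alone can give. The test set down beforehand decides nothing, as Prtn3 per Lyz2 was 3.09 [1.74, 5.48] times that of free RNA in reprogrammed day 5, an interval that reaches below 2-fold, and 0.98 [0.62, 1.55] times in untreated day 10, as free RNA would give. A biological account, in which reprogrammed cells are lost by day 10 and untreated tumours express the factor without doxycycline, stays open and was not tested.

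Interferon-gamma response genes in B-lineage-like cells differed between days by 3.80 on the log2 scale (3.20 on day 5 and -0.60 on day 10), and by 4.33 in the leukaemia lineage. Free RNA of host cells is argued against, as it could give at most 8.03% of the list's UMIs in any library. This holds if the barcodes under 1000 UMIs are free RNA only, since damaged cells rich in Xist among them would make the bound too low. A wider expression of Ifng by host cells in the same library cannot be told apart from other causes, since only 2 of the 4 libraries had the same rank for Ifng in all cells (7.02, 4.12, 149 and 120 CPM) as for the summed list (167, 1302, 3011 and 1895). That outcome rests on 1 T-like cell with 933 of the 954 Ifng UMIs of untreated day 5, and without the top cell of each library (0.155, 3.66, 135 and 94.2 CPM) all 4 ranks agreed, in a test chosen after the values were seen. The exchange of labels weighed for the mixed cells would also turn the day-10 sign, but it would leave the list far above the untreated day-5 level in both day-10 libraries. An influx of host cells by day 10 stays open as a biological explanation, and was not tested.

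Host cells gave similar reversals, which are given as values only. In phagocyte-like cells the type I interferon list differed between days by 4.89, the interferon-gamma list by 4.03, cytotoxic and effector genes by 2.51 and costimulatory and coinhibitory ligands by 1.88, while hypoxia and glycolysis genes differed by -1.67 and suppressive myeloid genes by -1.45, although the day-5 sign of the last (-0.83) turned to 1.38 with classes from each cell's own markers. In T-like cells the type I list differed by 3.70 and the interferon-gamma list by 1.99, and in whole libraries the interferon-gamma list differed by 4.19. In the leukaemia lineage, suppressive myeloid genes differed by 4.604 and cytokines and chemokines by 3.88, both lists holding genes of the mixed cells.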

How the results depend on the processing

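Leaving out the top 6% of doublet scores, subtracting free RNA, adding the mixed cluster, leaving out cells high in B-lineage genes and counting deep cells without clusters were chosen only after the results were seen. Leaving out a replicate could not be run, as each group is 1 library. No paired analysis was possible because the groups share replicate number 1 only and no test between groups was made. An additive fit of treatment and day was left out, not impossible. Depth limits the day-5 values of T-like cells (47 untreated cells) and phagocyte-like cells (57). The median of 2679 UMIs over the day-10 library labelled reprogrammed goes with its shallow unnamed cells, and its B-lineage-like cells had 17639 and its phagocyte-like cells 12154.

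The interferon-gamma list of B-lineage-like cells kept its sign in all 16 alternatives on both days, from 3.14 to 3.72 on day 5 and from -0.81 to -0.45 on day 10, and so did the class II list of phagocyte-like cells (0.0244 to 0.99 and 0.45 to 1.26). In T-like cells the cytotoxic list kept it in 15 of 15 on day 10 and 14 of 15 on day 5. T-like shares of named cells were higher in reprogrammed than in untreated on each day at every setting. Among host classes on day 10 the order was the other way at the main setting, at 44.5% in untreated and 33.5% in reprogrammed. Of the values of lists that answer a comparison, 89 stayed within their counting interval and 33 did not, and of such shares 45 did and 15 did not. Among other values, 1787 list medians stayed, 644 left their interval with the same sign or were too small to call, and 15 turned sign. For genes these numbers were 1109, 367 and 24, and for other shares 79 stayed and 33 did not. The values that follow are those that turned or, where they answer a comparison, left their interval. Ratios are log2, reprogrammed over untreated unless said otherwise, with the main value in parentheses where it differs in sign. The cause was not tested except where the alternative itself removes the cells or counts concerned.

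With 10 UMIs added, T-like cells on day 5 had -0.36 for Tiparp (1.23), -0.42 for Ube2l6 (2.74), -0.0296 for costimulatory ligands (1.04), -0.40 for cytotoxic genes (0.34) and -0.68 for myeloid surface genes (2.28). Without mitochondrial, ribosomal and receptor genes in the total, cytotoxic genes in T-like cells were at -0.27 and the whole-library interferon-gamma list at -0.73 on day 10. TMM scaling gave -0.23 and -0.80 for these, 3.39 for the latter on day 5, and -0.69 on day 10 and 0.29 for reprogrammed day 10 over day 5 for the B-lineage interferon-gamma list. Members from 10 UMIs gave -0.25 for costimulatory ligands in T-like cells on day 5 and -0.31 for exhaustion genes in phagocyte-like cells on day 10 (0.56). Members from 200 UMIs gave -0.73 for the B-lineage interferon-gamma list and -0.13 for suppressive genes (0.78) on day 10, and 3.64 for the whole-library interferon-gamma list on day 5.

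At Leiden resolution 0.5 on day 10, T-like shares were 7.74% and 14.1%, cytotoxic genes in T-like cells -0.53, and class II and exhaustion genes in phagocyte-like cells 0.59 and -0.0128. Resolution 2 gave -0.57 for the B-lineage interferon-gamma list on day 10. The looser filter gave -0.58 for it, 0.555 for the phagocyte class II list, a T-like share of 14.0% in reprogrammed and a mixed share of 5.31% in untreated, all on day 10. The stricter filter gave T-like shares of 0.411%, 7.75% and 7.80% in the first 3 libraries and 0.20 for proliferation in phagocyte-like cells on day 5 (-0.59), and with doublets kept the latter was 0.33 and class II 0.12. Without the top 6% of doublet scores, Ifng in T-like cells on day 5 was 1.39 (-6.10) and the mixed share of untreated day 5 was 0.0%.

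Cells thinned to 2000 UMIs gave 3.72 and, in whole libraries, 3.71 for the interferon-gamma list on day 5, -0.12 for cytotoxic genes on day 5 (0.54) and -0.31 for suppressive genes on day 10 in B-lineage-like cells, and in phagocyte-like cells 0.0244 and 0.62 for class II on both days, 0.0 for Lyl1 (-1.07) and 0.54 for Serpinb1a (-1.23) on day 5. With each cell scaled to the same total, the day-10 interferon-gamma list was -0.45 in B-lineage-like cells and -0.83 in whole libraries, class II in phagocyte-like cells 0.52, costimulatory ligands in whole libraries -0.0071 (0.63), and on day 5 Serpinb1a was 0.0941 and whole-library S100a9 -0.31 (1.87).

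Classes from each cell's own markers gave mixed shares of 0.635%, 2.72% and 4.12% in the libraries other than untreated day 10, -0.66 for the B-lineage interferon-gamma list on day 10 and -1.30 for myeloid surface genes in T-like cells on day 5. In phagocyte-like cells they gave 0.99 and 1.26 for class II, 1.38 for suppressive genes (-0.83), 0.34 for Adam8 (-1.90) and 0.50 for Serpinb1a on day 5, and -1.33 for Spp1 (1.76), 0.34 for Vcan (-1.09) and 0.0818 for Vpreb2 (-1.05) on day 10. Deep cells with myeloid UMIs and no Xist, with no B-lineage gene asked for, were 0.336%, 3.32%, 5.45% and 4.18%. Adding the mixed cluster to B-lineage-like cells gave 3.52 and -0.81 for the interferon-gamma list and -0.79 for suppressive genes on day 10.

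With free RNA subtracted the day-10 values were -0.69 for the B-lineage interferon-gamma list, -0.22 for cytotoxic genes in T-like cells, and 0.45 for class II, 1.54 for Dnajc9 (-1.05) and 1.21 for Phgdh (-1.05) in phagocyte-like cells. On day 5 it gave 0.0515 for class II and 0.29 for Phgdh (-1.03) there, and -3.41 for Hist1h3c in T-like cells (1.33). Without cells high in B-lineage genes, phagocyte-like cells on day 10 had 0.19 for the B-cell programme (-1.44), 0.62 for class II, 0.25 for Dnajc9, 0.0375 for Phgdh and 0.41 for Vpreb2, and on day 5 0.82 for Phgdh, 0.36 for Ptprcap (-1.40), 0.35 for Rasgrp2 (-1.08), 2.12 for Serpinb1a and 0.70 for Vpreb2 (-1.12).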

Other observations

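The NK-like cells, which were in none of the planned class comparisons and were looked at after the data had been seen, numbered 15, 284, 350 and 554. Gzmc, a granzyme of strongly activated NK cells, read 1065, 55.1, 1451 and 304 CPM and was lower in reprogrammed on both days, though the day-5 value rests on 15 untreated cells. Gzmd was seen mainly in untreated day 10 (0, 0, 1241 and 30.8), as was Spp1 (0, 25.1, 700.0 and 97.46). Ncr1, the activating receptor NKp46, read 317, 1397, 1518 and 594 and Gzmb 1123, 2766, 3835 and 1874, so both were highest in the untreated day-10 library. Tigit, an inhibitory receptor, differed in the opposite direction within each day, at 662, 114, 121 and 356. Cytotoxic genes had a median log2 ratio of 0.56 [0.17, 0.82] on day 5 and -0.39 [-0.51, -0.31] on day 10, and type I interferon genes 1.07 [0.28, 2.28] and -1.19 [-1.32, -0.89].

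A T-like cluster of 0, 0, 71 and 63 cells was seen on day 10 only and had Ifng, Xcl1, Ccl4, Gzmb and Ccl3 among its top genes. The cluster with the osteoclast genes Ctsk, Acp5 and Mmp9 held 53 of its 61 cells in the library labelled reprogrammed day 10, with Xist at 273 CPM. Mast cell or basophil-like cells with Mcpt8 and Hdc were 95 of 108 in reprogrammed day 5. Proliferation genes in B-lineage-like cells were at 0.21 [0.19, 0.23] on day 5 and -0.26 [-0.30, -0.25] on day 10, hypoxia and glycolysis genes at 0.14 [0.09, 0.18] and -0.37 [-0.40, -0.34], and dissociation and immediate-early genes at -0.10 [-0.14, -0.01] and 0.50 [0.37, 0.54].

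The remaining lists in B-lineage-like cells, reprogrammed over untreated on day 5 and then day 10, had medians of -0.05 and 0.20 for myeloid surface and granule genes, 0.18 and 0.22 for costimulatory and coinhibitory ligands, -0.42 and 0.10 for phagocytic receptors and lysosome, 0.04 and 0.36 for cytokines and chemokines, -0.22 and 0.78 for suppressive myeloid genes (the day-10 sign turned in 3 alternatives), 0.02 and 0.08 for p53 and apoptosis genes, and 0.31 and 0.18 for mitochondrially encoded genes. Lists named for T cells had 0.54 and 0.21 (cytotoxic, the day-5 sign turned with thinned cells), 0.17 and 0.62 (exhaustion), 0.46 and -0.38 (naive and memory) and 0.09 and 0.69 (regulatory), from few UMIs. In phagocyte-like cells proliferation stood at -0.59 and -0.32 (the day-5 sign turned with the stricter filter and with doublets kept), myeloid transcription factors at 0.15 and 0.03, myeloid surface and granule genes at 0.24 and -0.07, cytokines and chemokines at 0.69 and -0.22, immediate-early genes at 0.00 and -0.36, p53 genes at 0.12 and -0.24, and mitochondrially encoded genes at 0.05 and 0.27. T-like cells had 0.23 and -0.57 for class I presentation, 1.04 and -0.48 for costimulatory and coinhibitory ligands (the day-5 sign turned with 10 UMIs added and with members from 10 UMIs), -0.45 and -0.50 for hypoxia and glycolysis, 0.32 and 0.45 for immediate-early genes, 0.32 and -0.45 for cytokines and chemokines, and 0.23 and 0.12 for mitochondrially encoded genes.

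Negative correlations between the day-5 and day-10 ratios were also found in phagocyte-like cells (-0.581 over 437 genes), NK-like cells (-0.275 over 484 genes) and the leukaemia lineage (-0.768 over 728 genes), all across genes at least 2-fold apart on day 5 and without the interferon lists. The leukaemia lineage holds the mixed cells that raised the question of labels, so its value is not independent of them. Of interferon-linked genes only members of the lists were left out. In whole libraries, which move with the makeup of the pool, the Pearson value was -0.0781 over 1259 genes, with a Spearman value of 0.0881 and 67.2% of these genes having the same sign on both days. The same 3 values were -0.221, 0.0482 and 72.7% over 926 genes apart on day 10 and 0.195, -0.0161 and 46.5% over all 10967 genes with at least 50 UMIs, so whole libraries gave no clear direction. Spata7 was higher in reprogrammed in the leukaemia lineage on both days (1.06 and 1.00), so not every gene has the reversed order. The share of named cells in host classes was highest in the day-10 library labelled reprogrammed. That share depends on the sort and on the cells left unnamed, so it cannot bear on the labels.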
